A study of Mus musculus with 12 samples.

How the data were processed

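RNA sequencing covered 12 libraries from DRG of C57BL/6 mice aged 5 to 8 weeks. Per the labels' protocols, whole-DRG RNA had an integrity number above 7.5 and went into a TruSeq mRNA kit with 100-cycle paired-end reads. RNA of laser-captured neurons (16 µm sections stained with toluidine blue, neurons of at least 30 µm) had an integrity number between 6 and 7, and 100 ng per sample went into a RiboZero ScriptSeq kit with paired-end reads of 125 bases. Per the labels, the 3 replicates of whole DRG ran in lanes 4, 5 and 6, each lane holding the SH and the EE library of the same number. Captured SH libraries ran in lanes 3, 2 and 3 and captured EE libraries in lanes 1, 3 and 3. The submitters' processing notes name TopHat2 2.0.12, Bowtie2 2.2.3, SAMtools 0.1.19, HTSeq 0.6.0, edgeR 3.8.6, limma 3.22.7, R 3.1.1, FastQC 0.10.1 and the build mm10, without their roles.

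The deposited count tables give whole-number read counts per gene name for 44345 names, 1 table per preparation and 1 column per library. Their 5 summary rows name no gene and were left out of library sizes and tests. Reads outside any annotated feature made up 47.0 to 47.6% in whole DRG and 28.0 to 36.3% in captured neurons, and reads that did not map uniquely 8.49 to 8.99% and 11.0 to 15.2%. The authors' FPKM values of whole DRG were proportional to the counts and had 622 names with more than 1 row, of which the first by identifier was used. The authors' second table for captured neurons, named FPKM, held a signal equal to the counts times 1 constant per library, bringing each library to the total of the largest (29434351), with no division by gene length. It was therefore used as scaled counts. Column names of the whole-DRG tables carry the word Sham, which the labels do not explain, and columns were matched to samples by housing and number. No 2 libraries of a group were duplicates, the chi-square of their counts per degree of freedom being 3.95 to 21.5. No column belonged to another series.

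Counts were analysed with edgeR 4.0.16 in R 4.3.3, each preparation on its own. Genes were kept by filterByExpr, libraries were scaled by TMM, and EE was compared with SH by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The difference of the housing effect was the interaction contrast over all 12 libraries and the genes in both tables. CPM are TMM-normalised. Lists of genes (42, at least 5 measured members, covering ion channels, metabolism, stress, immunity, regeneration and cell type markers) were fixed before the data were examined, as were the designs, the alternatives and the rule for named genes. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Marker levels are medians of log2 CPM with 0.5 added. Alternatives were DESeq2 1.42.0 (adjusted p left NA where the tool gives NA), limma-voom, the edgeR likelihood ratio test, DESeq2 size factors, library size alone, no filter, a minimum average log2 CPM of 3, limma on log2 values of the second tables with 1 or 0.1 added and a minimum mean of 1, other thresholds, a replicate block, lane 3 alone and leaving out each library. Lane 3 alone was planned for genes and added for gene lists after seeing the data, and so were all alternatives for the lists of the difference between preparations.

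The rule for named genes took, per housing comparison, up to 10 genes per direction past the threshold with separated groups and an average log2 CPM of at least 1. Where fewer than 3 passed in a direction, it took the 5 with the smallest p. It added up to 4 members of each list with the smallest p, 13 genes in every comparison, genes past the threshold in both comparisons, and for the difference the 3 with the smallest p where none passed. The text names some of these genes and not all. Positions are from GENCODE vM21, whose build GRCm38 is the assembly of mm10.

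Replicate numbers pair the whole-DRG libraries because the labels give each number a shared lane, and deviations from the group means correlated at 0.33, 0.15 and 0.10 within numbers, although EE replicate 2 with SH replicate 3 reached 0.19. The pairing rests on the lanes. Correction for transcript length and GC content, chosen after seeing the data, used per-library offsets from splines with 4 degrees of freedom, and 95.9% and 95.6% of tested genes had reference values. Scripts were tested on simulated counts with 200 changed genes: in whole DRG the calls held 14 false ones among 201, in captured neurons 12 among 170 and for the difference 12 among 190. Depth was 11343579 to 17036481 reads in genes per whole-DRG library and 19296230 to 29434351 per captured library. Measured spread (common biological coefficient of variation) was 0.0741 and 0.121.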

Results

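Dorsal root ganglia (DRG) hold the cell bodies of the sensory neurons that serve the limbs and trunk. Ganglia of the sciatic levels were taken from C57BL/6 mice after 10 days in standard housing (SH) or in environmental enrichment (EE), a cage setting richer in stimuli than the standard one. RNA was sequenced from whole ganglia, pooled from 2 mice per library, and from neurons of at least 30 µm in diameter cut out of stained sections with a laser, from 3 mice per library. The design gave 12 libraries in 4 groups of 3. Between 11343579 and 17036481 reads lay in genes in the whole-ganglion libraries and between 19296230 and 29434351 in the captured-neuron libraries. The comparisons asked which transcripts differed with housing in the ganglion and in its large neurons. No label says whether the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

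In standard housing, captured neurons carried far fewer transcripts of most non-neuronal cells than whole ganglia did. Myelinating Schwann cell markers (22 genes) had a median of 3.84 ± 0.19 log2 CPM (CPM being counts scaled to library size; SD, n = 3) in captured neurons and of 6.11 ± 0.19 in whole DRG, which was 4.83-fold lower. Erythrocyte markers were 7.30-fold lower, fibroblast and meningeal markers 3.44-fold lower and macrophage markers 2.51-fold lower in captured neurons. Markers of satellite glia, which wrap neuronal cell bodies, lay at 6.81 ± 0.060 log2 CPM in captured neurons against 6.73 ± 0.060 in whole DRG by the median, while by the mean of log2 CPM they were lower by 0.35 in captured neurons. Nociceptor markers, genes of the small neurons that sense pain and itch, lay at 6.15 ± 0.10 in captured neurons and 5.61 ± 0.18 in whole DRG. Large-diameter neuron markers lay at 6.05 ± 0.11 and 6.82 ± 0.041, so that their median was lower after capture. Single neuronal genes went either way, scaled by library size alone. Ntrk3 (133 CPM in captured neurons, 23.8 in whole DRG) and Mrgprd (247 and 121) were higher after capture. Pvalb (35.3 and 116) and Calca (426 and 1487) were lower. Of 12 marker lists, 8 had a lower median in captured neurons, and 10 had a lower mean. The libraries also differed in kit, poly(A) selection for whole DRG and ribosomal RNA depletion for captured neurons, so capture and kit cannot be told apart and no test was made.

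In whole ganglia, Zbtb16 rose with enrichment. It encodes a zinc finger transcription factor (PLZF) that glucocorticoids are known to induce, and it went from 4.65 ± 1.47 CPM in SH to 12.5 ± 1.41 CPM in EE (SD, n = 3 per group). The log2 fold change was 1.43 (SE 0.19), with all 3 EE libraries above all 3 SH libraries (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0462). The gene lies on chromosome 9 from 48654297 to 48836222 in mm10, on the minus strand. It was the only gene of 15845 past the threshold in this fit, and 459 genes had an unadjusted p under 0.05 where 792 would be expected by chance.

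The genes that followed Zbtb16 in order of p did not pass the threshold. Among them were Mertk, a receptor kinase with which phagocytes engulf dying cells (log2 fold change 0.70, SE 0.15), the platelet chemokine gene Ppbp (2.08, SE 0.44), Id1 (0.59, SE 0.13) and the sterol carrier gene Stard4 (0.36, SE 0.086). On the lower side were Cxx1a (−0.42, SE 0.075), Hes5, a target of Notch signalling (−1.36, SE 0.25), Acer2 (−0.64, SE 0.17), Hhatl (−0.45, SE 0.13) and Gm16832 (−0.37, SE 0.094). Gm16832 runs antisense to a coding gene, and its reads cannot be separated from that gene without strand. When each EE pool was paired with the SH pool of the same number, which shared its sequencing lane, the replicate block brought the count from 1 to 32 genes, 23 higher and 9 lower in EE. Zbtb16 was among them, and so were Plin4, a lipid droplet gene (log2 fold change 1.11, adjusted p = 7.09e-10), Fkbp5, a glucocorticoid-induced chaperone (0.34, adjusted p = 0.00859), Mertk (0.69, adjusted p = 2.18e-07), Stard4 (0.36, adjusted p = 0.00115), Slc4a1, the anion exchanger of red cells (0.97, adjusted p = 0.000133), and on the lower side Hes5 (−1.35, adjusted p = 0.00312) and Ddit4, another glucocorticoid-responsive gene (−0.41, adjusted p = 0.00336), all by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Fold changes fell with GC content in this comparison (Spearman −0.24 across genes, which are not independent replicates), and the block with length and GC corrected gave 16 genes, 12 higher and 4 lower, without Hes5 (log2 fold change −1.28, adjusted p = 0.0698) and Ddit4 (−0.37, adjusted p = 0.402), whose fold changes moved little. Genes still past had larger adjusted p in that corrected fit (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). It was 0.000554 for each of Plin4, Zbtb16 and Mertk, 0.00486 for Stard4, 0.0159 for Slc4a1 and 0.0456 for Fkbp5. The same block, without that correction, gave 23 genes in another split of these libraries that parted all 3 pairs. Without the block, the call of Zbtb16 itself ended when SH replicate 1 (adjusted p = 0.0829), SH replicate 2 (0.0931), EE replicate 1 (0.0748), EE replicate 2 (0.125) or EE replicate 3 (0.105) was left out, with log2 fold changes from 1.18 to 1.51.

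Genes of cholesterol synthesis were a little higher in enriched whole ganglia, 23 of the 24 measured members having a positive log2 fold change. Their median was 0.12, and camera with a preset correlation called the list (adjusted p = 2.29e-13), while the adjusted p = 0.839 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 4 rose, among them Stard4 (from 132 ± 9.49 to 170 ± 18.9 CPM), Mvd, an enzyme of the pathway (from 47.3 ± 1.48 to 57.7 ± 4.46 CPM) and Insig1, which retains the sterol sensor in the endoplasmic reticulum (from 136 ± 10.5 to 163 ± 12.8 CPM).

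Blood cell markers were called higher as lists in enriched whole ganglia, unevenly between pools. The 10 measured erythrocyte markers had a median log2 fold change of 0.50, all 10 being positive, with Slc4a1 at 0.97 (SE 0.33) and Hba-a1 at 0.66 (SE 0.27). Hba-a1 has a near-identical neighbouring copy, so its own level is uncertain. The 15 lymphocyte and neutrophil markers had a median of 0.39, 14 being positive, with S100a8 at 0.48 (SE 0.28) and Retnlg at 0.57 (SE 0.32). Camera called both lists (adjusted p = 7.19e-10 and 1.84e-05), no member passed adjusted over the list alone or over all genes, and the adjusted p = 0.994 with an estimated correlation for each. With the replicate block, Slc4a1 (adjusted p = 0.000133), Hba-a1 (0.0167) and S100a8 (7.5e-05) rose over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and of these Hba-a1 did not pass with length and GC corrected too (log2 fold change 0.63 against 0.60 with the block alone, adjusted p = 0.772). Slc4a1 and S100a8 passed in that corrected fit with larger adjusted p (0.0159 and 0.0196, the same edgeR test). Between the replicates numbered 3, Hba-a1 was lower in EE (59.1 CPM) than in SH (96.9 CPM), scaled by library size alone. Relative to SH, the erythrocyte median was 0.74 in EE replicate 1, 0.93 in EE replicate 2 and −0.24 in EE replicate 3, below every SH library. It was still called without EE replicate 2 (median 0.21) and without EE replicate 3 (0.83). The lymphocyte and neutrophil call ended without EE replicate 2 (median 0.092) or SH replicate 3 (median 0.11). Its median was 0.82 without SH replicate 2 and 0.66 without EE replicate 3. Leaving out a library breaks its lane pair. Within each pair this list's median was higher in EE: 0.54 against 0.12, 0.86 against 0.71 and −0.15 against −0.66 for replicates 1 to 3, relative to SH.

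Camera called 9 of 41 lists in whole DRG, 7 higher and 2 lower, and 0 of them with an estimated correlation, with 10 called in the paired fit. Glucocorticoid-responsive genes (21 measured, median 0.15) were called (adjusted p = 0.0205, and adjusted p = 0.994 with an estimated correlation). Over all genes and adjusted over the list alone 1 of them rose, Zbtb16, while Plin4 stood at 1.16 (SE 0.38), Fkbp5 at 0.35 (SE 0.13) and Ddit4 at −0.38 (SE 0.15). This call ended without SH replicate 1 (median 0.077) and without EE replicate 2 (median −0.0016). Mitochondrially encoded genes (median 0.12, for example mt-Nd1 at 0.18, SE 0.096), interferon-stimulated genes (0.088, for example Stat2 at 0.14, SE 0.070) and skeletal muscle markers (0.62) were called higher. Satellite glia markers (−0.041, for example Ednrb at −0.27, SE 0.11, and Apoe at −0.16, SE 0.076) and extracellular matrix genes (−0.042, for example Nid2 at −0.34, SE 0.11, and Col14a1 at −0.32, SE 0.11) were called lower. Each of these 5 had an adjusted p = 0.994 with an estimated correlation and 0 members past the threshold over all genes or adjusted over the list alone. Each of these 5 calls also ended when some libraries were left out: mitochondrial genes without EE replicate 1 (median 0.049) or SH replicate 3 (0.039), interferon genes without SH replicate 1 (0.064) or EE replicate 2 (−0.025), muscle markers without SH replicate 1 (0.091) or EE replicate 2 (−0.43), satellite glia without SH replicate 1 (−0.065), SH replicate 2 (−0.0022) or EE replicate 1 (0.012), and matrix genes without EE replicate 1 (0.014) or SH replicate 2 (0.028). With length and GC corrected, the matrix call (median −0.0024, adjusted p = 0.0613) and the interferon call (0.080, adjusted p = 0.0637) ended as well. Within lane pairs the mitochondrial median was higher in EE each time, while the interferon, muscle and satellite glia medians changed direction between pairs. The matrix median, relative to SH, was lower in EE for replicates 1 (−0.19 against −0.13) and 2 (0.11 against 0.14). For replicate 3 it was −0.042 in both libraries.

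None of the genes of injury, growth and transmission named in advance passed the threshold in whole DRG. Atf3, which sensory neurons switch on after axon injury, stood at 0.30 (SE 0.10), and the growth cone gene Gap43 at −0.078 (SE 0.066). Sprr1a (−0.27, SE 0.21), Jun (−0.0053, SE 0.069), Fos (−0.051, SE 0.13), Bdnf (0.11, SE 0.071), Npy (0.076, SE 0.62) and Gal (−0.0052, SE 0.13) were likewise not past it. The acetyltransferase genes Crebbp (0.026, SE 0.093) and Ep300 (0.030, SE 0.087), the proprioceptor marker Pvalb (0.063, SE 0.077) and the peptidergic marker Calca (0.012, SE 0.066) were not either. On simulated counts of this comparison the test recovered 100% of 2-fold and 87% of 1.5-fold changes. Yet measured changes larger than 2-fold (Ppbp, Hes5 and Plin4) did not pass. The simulated changes were placed only in genes above a minimum level, which Ppbp and Hes5 (average log2 CPM 1.24 and 1.17) did not reach. Plin4 (4.08) did reach it. The simulated share therefore does not describe genes as low or as variable as these.

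**Figure D1:**
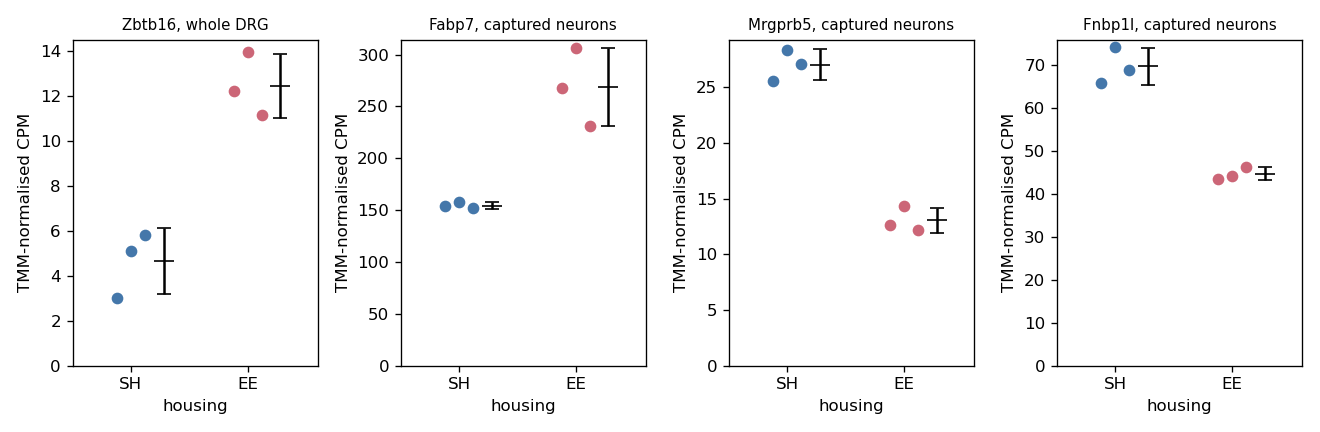
TMM-normalised CPM of the 4 genes past the threshold, Zbtb16 in whole DRG and Fabp7, Mrgprb5 and Fnbp1l in captured neurons, on linear axes from 0. Points are the 3 libraries of each housing and the black marks give mean and SD. In each panel the EE libraries lie wholly above or wholly below the SH libraries, for example 12.5 ± 1.41 against 4.65 ± 1.47 CPM for Zbtb16.

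In captured large-diameter neurons, enrichment went with more Fabp7 and less Mrgprb5 and Fnbp1l. Fabp7, a fatty acid binding protein that marks satellite glia, rose from 154 ± 2.97 to 269 ± 37.6 CPM (SD, n = 3 per group, log2 fold change 0.80, SE 0.094). Mrgprb5, a receptor of the Mas-related family expressed in small sensory neurons, fell 2.07-fold, from 27.0 ± 1.39 CPM in SH (log2 fold change −1.05, SE 0.098), and it has close paralogs that could share its reads. Fnbp1l, which couples membrane curvature to actin, fell from 69.8 ± 4.25 to 44.7 ± 1.48 CPM (log2 fold change −0.64, SE 0.074). The adjusted p was 0.0322 for Fabp7, 0.0119 for Mrgprb5 and 0.0322 for Fnbp1l (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and in each case the 3 EE libraries lay on one side of the 3 SH libraries.

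These 3 genes lie on chromosome 10 from 57784881 to 57788450 (Fabp7), on chromosome 7 from 48167983 to 48169019 (Mrgprb5) and on chromosome 3 from 122538719 to 122619715 (Fnbp1l) in mm10. They were the only ones of 16186 past the threshold, although 106 genes had an adjusted p under 0.1 and 2576 an unadjusted p under 0.05, where 809 would be expected. Genes are not independent, and another split of these libraries gave 1617 at that unadjusted p. Housing groups did not overlap for 21.1% of genes, against 10% by chance. The count depended on EE replicate 1: without it 602 genes passed, 281 higher and 321 lower, and within sequencing lane 3, which held 2 SH and 2 EE libraries and not that one, 658 passed, each time including all 3. With length and GC corrected 2 passed, and Fabp7 did not (0.66, adjusted p = 0.0815). Without any 1 of the SH libraries 0 genes passed, and without EE replicate 2 or EE replicate 3 there was 1.

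Next in order of p and not past the threshold were Aif1l (log2 fold change 0.68, SE 0.098), the histone gene Hist1h2bc (0.48, SE 0.076), whose family members are near copies, the sodium pump regulator Fxyd7 (0.52, SE 0.086) and the glycolytic gene Aldoc (0.45, SE 0.077). On the lower side followed Fmnl1 (−0.73, SE 0.10), St6gal2 (−0.85, SE 0.13) and 2510009E07Rik (−0.51, SE 0.079). All 7 of them passed within lane 3.

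Nociceptor markers were lower in captured neurons of enriched mice, by 1.39-fold at the median of 31 genes (log2 fold change −0.48). Adjusted over the list alone 18 of them fell and 13 did not pass, and over all genes 0 passed. Among the 18 were Runx1, the transcription factor of non-peptidergic nociceptors (from 178 ± 22.7 to 115 ± 10.3 CPM), Il31ra, an itch receptor (from 55.5 ± 6.32 to 29.0 ± 6.83 CPM), Cysltr2 (from 22.7 ± 2.63 to 12.6 ± 2.40 CPM) and Plxnc1 (from 690 ± 85.2 to 485 ± 31.0 CPM). Not all members fell, 3 having a positive log2 fold change. Scaled by library size alone, the peptidergic marker Calca stood at 426 ± 49.4 CPM in SH and 512 ± 83.1 in EE. Trpv1 overlapped between housings (162 ± 26.4 and 148 ± 53.4 CPM). Camera called the list (adjusted p = 2.38e-20), with adjusted p = 0.505 with an estimated correlation. The nociceptor sodium channel genes Scn10a (−0.45, SE 0.095) and Scn11a (−0.53, SE 0.11) moved the same way without passing over all genes, except within lane 3 (adjusted p = 0.00114 and 0.000403, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). EE replicate 1 lay at −0.18 on the list's median relative to SH, against −0.64 and −0.57 for EE replicates 2 and 3, and the median within lane 3 was −0.49 (called).

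Markers of large-diameter neurons were higher in the same libraries, with a median log2 fold change of 0.39 over 28 genes, or 1.31-fold. Adjusted over the list alone 11 rose and 1 fell, and over all genes 0 passed. The 11 included the neurofilament genes Nefl (from 4426 ± 502 to 6136 ± 681 CPM) and Nefm (from 1881 ± 244 to 2735 ± 573 CPM), Ldhb (from 125 ± 15.6 to 167 ± 16.3 CPM) and Vamp1 (from 225 ± 25.4 to 309 ± 46.0 CPM). Scn1a, a sodium channel gene prominent in large neurons, stood at 0.43 (SE 0.096). Camera called the list (adjusted p = 1.5e-09, and adjusted p = 0.505 with an estimated correlation). EE replicate 1 lay at 0.091 relative to SH, and EE replicates 2 and 3 at 0.51 and 0.56, and the median within lane 3 was 0.42 (called).

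Nuclear-encoded genes of energy metabolism were higher in captured neurons of enriched mice. All 75 measured nuclear-encoded genes of oxidative phosphorylation had a positive log2 fold change, with a median of 0.25, and adjusted over the list alone 38 rose, over all genes 0. Cox7b went from 132 ± 14.6 to 176 ± 11.1 CPM, Uqcrh from 54.2 ± 6.80 to 72.7 ± 4.10 CPM, Ndufv2 from 129 ± 11.1 to 161 ± 3.69 CPM and Cox5a from 35.6 ± 1.28 to 44.8 ± 1.03 CPM. Camera called the list (adjusted p = 1.99e-26, and adjusted p = 0.509 with an estimated correlation). Glycolysis and TCA cycle genes (39 measured) had a median of 0.093, with 12 past adjusted over the list alone and 0 over all genes, among them Mdh1 (0.34, SE 0.065), Eno2 (0.31, SE 0.063), Pkm (0.35, SE 0.076) and Aldoc, and camera called them (adjusted p = 7.07e-06, and adjusted p = 0.509 with an estimated correlation). Shorter transcripts had higher fold changes in this comparison (Spearman −0.22 across genes, which are not independent replicates), and with length and GC corrected, an alternative chosen after seeing the data, the oxidative phosphorylation median was 0.16. Within lane 3 it was 0.16 as well, and that of glycolysis and TCA cycle genes 0.054, both called, and without EE replicate 1 the latter was 0.059. Mitochondrially encoded genes were not called over the 6 libraries (median 0.058, adjusted p = 0.283, and −0.11 with length and GC corrected), but were within lane 3 (0.15). The oxidative phosphorylation level also followed the share of reads outside annotated features, lower in captured EE libraries (28.0, 33.8 and 30.9%) than in SH (32.1, 36.3 and 34.5%) on average.

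Satellite glia markers were higher in enriched captured neurons, with a median of 0.18 over 21 genes. Adjusted over the list alone 9 rose, and over all genes 1, which was Fabp7. S100b went from 334 ± 38.7 to 474 ± 25.7 CPM, Dbi from 81.6 ± 4.66 to 117 ± 13.9 CPM and Apoe from 1264 ± 117 to 1623 ± 29.0 CPM. Camera called the list (adjusted p = 1.03e-09, and adjusted p = 0.505 with an estimated correlation), and the median within lane 3 was 0.27. Heat shock and chaperone genes (20 measured, median 0.19) had 4 past adjusted over the list alone and 0 over all genes, with Dnajb4 at 0.42 (SE 0.076), Hspb1 at 0.30 (SE 0.069) and Fkbp4 at 0.28 (SE 0.082), and were called (adjusted p = 3.61e-06, and adjusted p = 0.505 with an estimated correlation). Proteasome genes (31 measured, median 0.14, for example Psmb7 at 0.31, SE 0.082) were called as well (adjusted p = 1.16e-05, and adjusted p = 0.771 with an estimated correlation), with 0 past adjusted over the list alone or over all genes. Within lane 3 heat shock genes were called (0.12) and proteasome genes were not (0.039, adjusted p = 0.169), and with length and GC corrected the proteasome median was 0.058 (adjusted p = 0.0473). Without EE replicate 1 the medians were 0.074 for the proteasome and 0.30 for satellite glia, both still called. EE replicate 1, with the fewest reads outside annotated features (28.0%), had the highest proteasome and heat shock medians (0.25 and 0.28 relative to SH). SH replicate 2, with the most such reads (36.3%), had the lowest (−0.078 and −0.080). A relation of these lists to that share was not tested.

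Calcium and potassium channel genes were lower as groups, and the list of voltage-gated sodium channels was not called (median −0.17, adjusted p = 0.283, 3 higher and 4 lower adjusted over the list alone) except within lane 3 (−0.21, adjusted p = 0.0110). Of 20 voltage-gated calcium channel genes (median −0.18) 3 fell and 1 rose adjusted over the list alone, 0 over all genes. Cacna1i (−0.99, SE 0.20), Cacna1b (−0.50, SE 0.11) and Cacna1c (−0.42, SE 0.095) were lower and Cacnb2 (0.47, SE 0.15) was higher. Of 47 potassium channel genes (median −0.14) 10 fell and 1 rose adjusted over the list alone, 0 over all genes, with Kcnt1 at −0.40 (SE 0.074), Kcnd1 at −0.33 (SE 0.077) and Kcnd3 at −0.49 (SE 0.12). Camera called both lists (adjusted p = 0.00559 and 0.0112), with adjusted p = 0.571 and adjusted p = 0.505 with an estimated correlation, and neither call was kept with length and GC corrected, where the medians were −0.13 and −0.10 (adjusted p = 0.0918 and 0.290). Neither was called within lane 3 (medians −0.13 and −0.16, adjusted p = 0.0567 and 0.0584), and the calcium channel call also ended without SH replicate 2 (median −0.11). Like nociceptor markers, both lists were highest in SH replicate 2 (0.14 and 0.052 relative to SH) and lowest in EE replicate 2 (−0.26 and −0.23). Whether they moved with those markers was not tested.

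Camera called 14 of 42 lists in captured neurons, 10 higher and 4 lower, and 0 with an estimated correlation; within lane 3 it called 12, of which 8 were among the 14, ribosomal proteins in the opposite direction. Skeletal muscle markers had a median of −4.62 over 13 genes, all 13 past adjusted over the list alone and 0 over all genes, and their call (adjusted p = 0.000163, and adjusted p = 0.771 with an estimated correlation) rested on SH replicate 2, where Ttn reached 1412 CPM. Without that library the median was 0.046 and within lane 3 it was 0.14. Ribosomal protein genes (77 measured, median 0.074, for example Rpl38 at 0.31, SE 0.096) were called higher over all 6 libraries (adjusted p = 0.00124, and adjusted p = 0.971 with an estimated correlation). Within lane 3 they were called lower (median −0.082), without EE replicate 1 or SH replicate 2 they were not called (−0.036 and 0.031), and 0 members passed over all genes or adjusted over the list alone. Macrophage markers (0.22, for example Cx3cr1 at 0.84, SE 0.26), markers of the central nervous system (0.41, for example Aqp4 at 0.42, SE 0.10) and replication-dependent histones (0.20) were called higher (adjusted p = 0.0287, 0.0250 and 0.0250). Their values were adjusted p = 0.720, adjusted p = 0.505 and adjusted p = 0.720 with an estimated correlation, with 0, 2 and 1 members past adjusted over the list alone and 0 over all genes. These 3 calls ended with some libraries left out: macrophage markers without SH replicate 3 (0.11) or EE replicate 1 (0.085), central nervous system markers without SH replicate 1 (0.30) or SH replicate 3 (0.25; still called at 0.17 without EE replicate 2), and histones without SH replicate 2 (0.13), SH replicate 3 (0.12), EE replicate 1 (0.16) or EE replicate 3 (0.18). Within lane 3 central nervous system markers were called (0.39), macrophage markers (0.089) and histones (0.12) were not. With length and GC corrected camera called 10 lists, and not ribosomal proteins (−0.021, adjusted p = 0.569), macrophage markers (0.14, adjusted p = 0.195) or histones (0.11, adjusted p = 0.379).

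**Figure D2:**
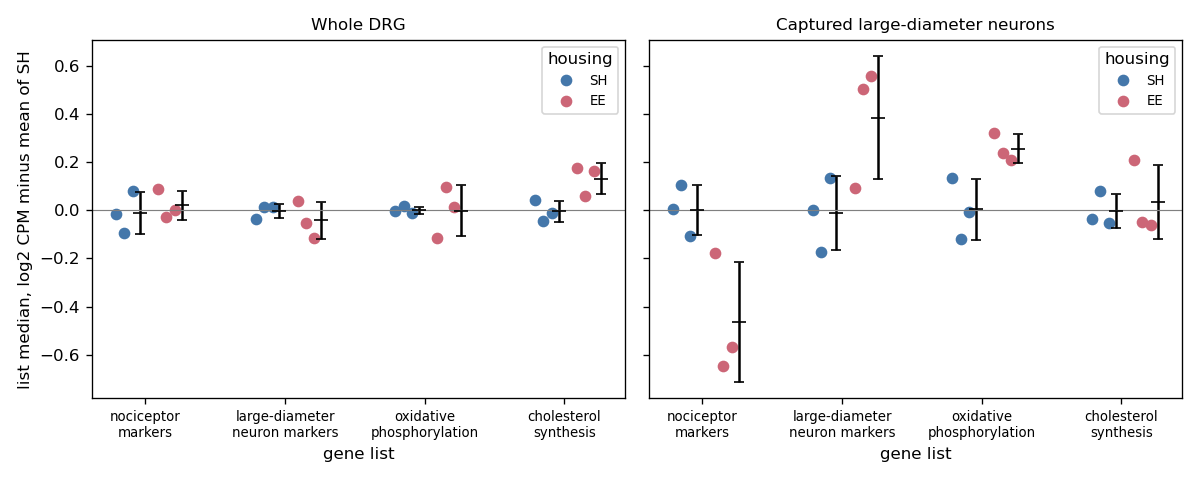
Median over the members of 4 gene lists in each of the 12 libraries, in log2 CPM relative to the mean of the SH libraries of the same preparation. Points are libraries, black marks give mean and SD over the 3 libraries of a group. In captured neurons EE replicates 2 and 3 lie at −0.64 and −0.57 for nociceptor markers and at 0.51 and 0.56 for large-diameter neuron markers, with EE replicate 1 nearer to SH.

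The genes of injury and growth named in advance did not pass the threshold in captured neurons either. Atf3 (−0.092, SE 0.45) and Sprr1a (0.43, SE 0.84) had wide errors. Gap43 (0.24, SE 0.13), Jun (0.25, SE 0.19), Fos (0.58, SE 0.19), Bdnf (0.0034, SE 0.14) and Gal (−0.18, SE 0.25) had smaller errors, and Npy was too low to test. The acetyltransferase genes Crebbp (−0.24, SE 0.11) and Ep300 (−0.29, SE 0.10), and Pvalb (0.83, SE 0.31) and Calca (0.26, SE 0.11) did not pass over the 6 libraries. Pvalb stood at 27.8 CPM in EE replicate 1, at 83.9 and 78.4 CPM in EE replicates 2 and 3 and at 35.4 ± 1.27 CPM in SH, and within lane 3 it passed (1.21, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.51e-05). On simulated counts of this comparison 92% of 2-fold and 66% of 1.5-fold changes were recovered. Yet the 13 skeletal muscle markers, with a median of −4.62, did not pass over all genes. The simulation also gave no library a deviation shared by many genes, as EE replicate 1 had here. The simulated share therefore does not describe the power in these libraries.

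The response to housing was then compared between whole ganglia and captured neurons. The 3 genes with the smallest p for a difference were Fnbp1l, at 0.094 in whole DRG and −0.64 in captured neurons (difference −0.75, SE 0.11), Fxyd7 (−0.14 and 0.52, difference 0.64, SE 0.10) and Fabp7 (−0.14 and 0.80, difference 0.92, SE 0.16). None passed the threshold (edgeR quasi-likelihood interaction test with Benjamini-Hochberg adjustment, adjusted p = 0.0773, 0.0884 and 0.0884). Of 17412 genes 0 passed and 2034 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 145, and without captured-neuron EE replicate 1 the edgeR test called 233. Simulated 2-fold differences were recovered in 89% of cases. That simulation too held no deviation shared by many genes of a library, so its share does not describe these libraries. Camera called 14 of 42 lists for the difference and 0 with an estimated correlation. Nociceptor markers differed by −0.49 and oxidative phosphorylation genes by 0.26 (captured neurons minus whole DRG, adjusted p = 3.46e-18 and 6.4e-22, with adjusted p = 0.382 and adjusted p = 0.425 with an estimated correlation).

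Across 14800 genes tested in both preparations, log2 fold changes had a Pearson correlation of −0.14 and a Spearman correlation of −0.080, with the same sign in 46.6% (genes are not independent replicates). No gene was past the threshold in both. At an unadjusted p under 0.05, 11 genes were higher in both where 14.9 were expected for independent lists (Fisher's exact test, two-sided p = 0.342), and 14 were lower in both where 19.2 were expected (p = 0.277, the same exact test). The correlation depended on single libraries, being −0.30 without whole-DRG SH replicate 3 and −0.037 without captured-neuron SH replicate 2.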

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

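The counts over other splits of the libraries were planned before the data were examined, except that for the correlation between preparations. The test of the difference over gene lists, the counts over splits that kept neither real split, and the tests of length and GC, lane, muscle, neuron mix, RNA quality and glia below were chosen after the results were seen.

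The housing effect differed between preparations for 14 lists by camera on the interaction contrast, and for 0 with an estimated correlation. Medians of the difference, captured neurons minus whole DRG, were 0.26 for oxidative phosphorylation, 0.40 for large-diameter neuron markers, 0.22 for satellite glia, 0.22 for heat shock genes, 0.076 for glycolysis and TCA cycle, 0.13 for the proteasome, 0.061 for ribosomal proteins, 1.23 for adipocyte markers and 0.24 for histones. They were −0.49 for nociceptor markers, −5.57 for skeletal muscle markers, −0.25 for calcium channels, −0.18 for potassium channels and −0.079 for cholesterol synthesis. Adipocyte markers were near the floor in captured SH (−0.52 log2 CPM). Relative to SH, their median was 1.39, −0.24 and 0.064 in captured EE replicates 1 to 3, over 5 measured genes. The captured muscle change rested on SH replicate 2, without which its median was 0.046. Among 100 drawn combinations of splits of the libraries, the real one included, 52 gave as many lists as the 14, and the highest other gave 29. Among the 83 that kept neither real split 41 gave as many, and among the 29 of these that parted all 3 lane pairs 15 did, so chance is not excluded for the number of lists. As many genes with an unadjusted p under 0.05 as the 2034 came from 7 of the 100, the highest other giving 3119. Of the other 6, 4 kept the real split of the captured libraries and so held its housing effect, and the remaining 2 did not part all 3 lane pairs. With neither real split kept and all 3 pairs parted the highest was 1468. These splits leave open whether chance accounts for the number of genes. The correlation of housing effects between preparations, −0.13 on log2 CPM differences, was reached in absolute value by 17 of 100 pairs of splits, the highest other being 0.22, and by 13 of the 81 pairs with neither real split, so chance is not excluded.

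Other splits of the 6 libraries of a preparation number 10 with the real one, too few for a share under 0.05. In whole DRG the real split gave 1 gene, 4 of the 10 gave as many, and the highest other gave 33. That split set SH replicates 1 and 2 with EE replicate 1 apart from the rest and points to a structure of the samples. All 10 splits gave as many lists as the 9, the highest other giving 26. Of the splits that also part all 3 lane pairs, the other 3 gave 0 genes each without the replicate block and 23, 1 and 0 with it, against 32. In captured neurons the real split gave 3 genes, 1 of the 10 gave as many, and the highest other gave 0. At an unadjusted p under 0.05 it gave 2576 genes, and the highest other gave 1617. For lists it gave 14, 5 of the 10 gave as many, and the highest other gave 15.

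Nociceptor markers were lower and large-diameter neuron markers higher in captured neurons of enriched mice. Transcript length and GC content as the whole cause is argued against by the median of the nociceptor markers with offsets for both, −0.47, still called by camera (adjusted p = 1.71e-24), and sequencing lane by the median of −0.49 within lane 3. A different mix of captured neurons remains open: the 2 marker means moved in opposite directions across the 6 captured libraries (Pearson r = −0.97, exact permutation p = 0.00833, Spearman −0.89, exact p = 0.0333, adjusted p of the Pearson test over 3 relations 0.025, r = −0.78 without the 2 libraries farthest from the median), and whole DRG had a nociceptor median of 0.026. The relation over the 6 libraries holds the housing difference, with EE replicates 2 and 3 at its end. Within housing groups r was −0.96, so the relation does not rest on that difference alone. A housing effect within neurons stays untested.

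Oxidative phosphorylation genes were higher in captured neurons of enriched mice. Offsets for transcript length and GC content lowered the median from 0.25 to 0.16, still called (adjusted p = 2.17e-13), which argues against that trend as the whole cause and leaves it as a part. SH replicate 2 had the lowest level of the list among the captured libraries (−0.12 relative to SH), and without it the median was 0.20. That argues against skeletal muscle RNA in SH replicate 2 as the whole cause. Leaving the library out cannot tell its muscle RNA from its other traits. A different mix of captured neurons is open. The list's level and the difference between the marker means had a Pearson r of 0.56 across the 6 captured libraries (exact permutation p = 0.233, Spearman 0.49, exact p = 0.356, r = 0.55 without the 2 farthest). Within housing groups r was −0.28, so the positive relation came from the difference between housings. The 6 libraries are too few to decide. RNA quality is open too, and the share of reads outside annotated features was used as a stand-in, since integrity is known only as a range. That share is no direct measure of quality: whole DRG, with RNA of higher integrity and another kit, had 47.0 to 47.6%. The list fell as that share rose across the 6 captured libraries (Pearson r = −0.87, exact permutation p = 0.0264, adjusted p 0.0396 over 3 relations, Spearman −0.83, exact p = 0.0583, r = −0.55 without the 2 farthest, r = −0.81 within housing groups). An effect of housing stays among the open explanations.

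Cholesterol synthesis genes were higher in whole DRG of enriched mice. With the replicate block and offsets for length and GC content together the median was 0.12 (adjusted p = 1.24e-22), which argues against that trend. More Schwann cells or satellite glia in the EE pools is not decided by their marker medians, −0.023 (bootstrap SE 0.021) and −0.041 (SE 0.017), neither being above 0. These SEs resample genes and do not measure the spread between pools. Relative to SH, the Schwann median was −0.29, 0.22 and −0.024 in the EE libraries and −0.021, 0.12 and −0.11 in the SH libraries. Glia, other cell types and an effect of housing stay open. The list's call may reflect correlated genes, since the 9 lists called in whole DRG fell to 0 with an estimated inter-gene correlation.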

How the results depend on the processing

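In whole DRG, 1 gene passed in the chosen fit. Library size alone gave 0, no low-count filter 48, the likelihood ratio test 5, limma on FPKM 0 with 1 added, 0 with 0.1 added and 0 unfiltered, and an unadjusted p under 0.05 gave 459. The replicate block, pairing libraries by lane, gave 32, and with length and GC correction 16. Leaving out 1 library gave 0 to 2 genes. Of lists, 9 were called, 0 with an estimated correlation, 0 with fry and 5 to 19 with 1 library left out.

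In captured neurons, 3 genes passed. No filter gave 902, a minimum average log2 CPM of 3 gave 1, DESeq2 522, the likelihood ratio test 389, limma on scaled counts 168 with 1 added, 55 with 0.1 added and 306 unfiltered. An adjusted p under 0.1 gave 106, an unadjusted p under 0.05 gave 2576, lane 3 alone 658 and 1 library left out 0 to 602. A replicate block gave 0, but replicate numbers do not pair these libraries. Of 14 lists, 0 were called with an estimated correlation and 0 with fry.

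For the difference between preparations, 0 genes passed, DESeq2 gave 145 and 1 library left out 0 to 233. Of 14 lists, 0 were called with an estimated correlation and 0 with fry. The correlation of housing effects ranged from −0.30 to −0.037 with 1 library left out.

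Among genes, signs reversed only for those that had not passed. The lists that reversed had all been called by camera at the preset correlation, and only called lists were checked. In whole DRG the reversals were Jun (0.021 with length and GC correction, 0.020 with the block too), Npy (−0.63 with limma-voom, −0.28, −0.66 and −0.28 on FPKM, −0.064 with the block, −0.035 with block and correction), Gal (0.0061 with limma-voom, 0.013 corrected, 0.016 with the block too) and Calca (−5.5e-05, −5.6e-05 and −5.5e-05 on FPKM). With 1 library left out the ranges were Crebbp −0.039 to 0.071, Ep300 −0.036 to 0.080, Jun −0.039 to 0.033, Npy −1.62 to 0.64, Gal −0.095 to 0.16, Pvalb −0.023 to 0.12, Calca −0.039 to 0.047, interferon genes −0.025 to 0.19, matrix genes −0.097 to 0.028, glucocorticoid-responsive genes −0.0016 to 0.27, satellite glia markers −0.075 to 0.012, muscle markers −0.43 to 3.49.

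In captured neurons the reversals were Atf3 (0.011 with limma-voom, 0.025, 0.025 and 0.025 on scaled counts, 0.031 with a block, 0.65 in lane 3), Sprr1a (−0.32 with limma-voom, −0.13, −0.18 and −0.13 on scaled counts), Bdnf (−0.016 with limma-voom, −0.0050 with a block), Gal (0.056 in lane 3), ribosomal proteins (−0.082 in lane 3, −0.021 corrected) and muscle markers (0.14 in lane 3). With 1 library left out the ranges were Atf3 −0.57 to 0.54, Sprr1a −1.36 to 1.00, Bdnf −0.16 to 0.13, Gal −0.42 to 0.052, ribosomal proteins −0.036 to 0.14, muscle markers −5.19 to 0.046. Muscle markers reversed because SH replicate 2 was left out, and for the other values the cause was not tested.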

Other observations

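Of the 4 clock genes chosen by the rule, Per2 and Per3 were lower in captured neurons of enriched mice: Per2 went from 16.9 ± 2.13 to 10.4 ± 0.683 CPM and Per3 from 26.7 ± 2.11 to 18.2 ± 1.19 CPM (SD, n = 3). Both fell adjusted over the list alone, where Nr1d1 (log2 fold change 0.68, SE 0.22) and Cry1 (−0.36, SE 0.13) did not pass, and not over all genes (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0898 for each), and the list of 18 clock genes was not called by camera (adjusted p = 0.243), 6 members being positive and 12 negative. Per2 and Per3 passed over all genes within lane 3 (adjusted p = 0.0026 and 0.00432). In whole DRG the list median was 0.038.

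Skeletal muscle markers varied widely between libraries of the same housing. Ttn was at 1412 CPM in captured SH replicate 2 and at 12.5 CPM in the lowest captured SH library. The list's median relative to SH was 2.92 in whole-DRG EE replicate 2, 2.70 in SH replicate 3 and −1.87 in SH replicate 1.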
